A study of Mus musculus with 2 samples.

How the data were processed

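Histone H3 trimethylated at lysine 4 (H3K4me3), a mark of active and poised promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in hearts dissected from mouse embryos at embryonic day 11.5. The samples form 1 group of 2 biological replicates. Per the labels, the strain was B6NCrl, hearts of male and female embryos were pooled, replicate 1 held the hearts of 109 embryos, library fragments were 300 to 500 bp long, and an experiment that could serve as control was named.

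The deposited files are 4 peak lists on the mouse assembly mm10. Per the deposited README text, 1 list was derived from each replicate's own alignments, the pooled list from the alignments of both replicates, and the replicated list from the lists of both replicates and the pooled list. The aligner, the peak caller and its threshold are not given in the sources used here. Each of the 25868 replicated peaks was present in the pooled list with the same ends and values, so the replicated list was read as the pooled peaks kept by the authors on replication. The signal column of the deposited lists was read as the fold enrichment of each peak over control, a ratio made by the authors' peak caller. The deposited lists also give the -log10 of each peak's p and q as the authors' caller computed them. Fold enrichment is therefore the authors' value for a peak, and it was used to describe, rank or filter peaks, to match random lists and to compare genes and gene lists within 1 peak list. The lists hold no read counts, so sequencing depth is unknown, and no interval or detection limit that needs depth is given. The lowest -log10 q was 0.235 in the replicated list, and 0.808% of its peaks lay below a -log10 q of 2, so the deposited threshold was permissive.

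Peaks were placed against the GENCODE M21 annotation of GRCm38, the assembly named mm10 in the files; every peak ended within the length of its chromosome. Chromosomes 1 to 19, X and Y were used, with 21938 protein-coding genes. A gene was called marked when a replicated peak overlapped, by at least 1 bp, the 1 kb on either side of any of its annotated transcription start sites (TSSs). No check was made at this step for the promoter of a neighbouring gene, to which such a peak could also belong. Replicated peaks separated by at most 500 bp were joined into domains, and a gene's domain was the longest that overlapped its promoter window. A gene's fold enrichment was the highest among its promoter peaks. Domain length and fold enrichment were also measured in each replicate's own list. These give a mean ± SD (n = 2) where one is printed. Gene values with no SD and no replicate named are from the replicated list, and some lengths differed widely between replicates. A domain in the replicated list can be longer than in either replicate, since its peaks were called on both replicates together. Some genes named below as unmarked had a promoter peak in 1 replicate's own list. They were Casq2, Robo4, Upk1b, Slc17a6, Ddx4, Hba-a1, Hoxc8 and Hoxc11.

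Promoters were put in CpG classes from 500-bp windows moved by 10 bp within 1 kb of the most 5' TSS. High-CpG promoters held a window with an observed/expected CpG ratio above 0.75 and a GC fraction above 0.55, and low-CpG promoters held no window above 0.48. Peak locations were assigned in the order promoter, exon, intron and intergenic, with exact (Clopper-Pearson) 95% binomial intervals that treat peaks as independent.

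The 24 gene lists, the comparisons, the tests and the alternatives were fixed before the data were examined, apart from fold enrichment in place of length for the pairs of lists. For the 23 protein-coding lists, the marked share was compared with that of all other protein-coding genes by Fisher's exact test. Median domain length was compared with that of all other marked genes by a permutation test of 100000 resamples, in lists with at least 5 marked members. Membership of the longest 5% of domains was compared by Fisher's exact test among marked genes. The 6 planned pairs of lists were compared by the same tests. All tests were two-sided, with Benjamini-Hochberg adjustment over lists or over pairs and a threshold of 0.05. The smallest p that the permutations could give was 2e-05. Expected values for promoters of the same CpG class came from 10000 random lists, a permutation of list membership within CpG classes, whose smallest p was 0.0002. For marking, these lists were drawn from all protein-coding genes of a class, list members included. Of the 7094 low-CpG genes, 1414 were chemosensory receptor genes with 1 marked, which lowers the marked share expected of low-CpG promoters in every list. Genes are not replicates, so these p-values describe this peak list and not variation between embryos. With 1 group there was no differential test between conditions.

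Named genes followed a rule with 3 parts. The first took the 20 longest replicated domains at protein-coding promoters that were also in the longest 5% in both replicates, and the next took the 10 genes with the highest fold enrichment by the lower of the 2 replicates. The last took, in each list, up to 4 marked members with the longest domains and up to 4 unmarked members; other members could be named where their list is described. One noncoding symbol of the 24th list, Gata6os, was not matched in the annotation, so it has no value.

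Alternatives were a -log10 q of at least 5, the pooled list, each replicate's list alone, promoter windows of 500 and 2500 bp, only the most 5' TSS, no joining and joining up to 2000 bp, CpG-matched random lists, and fold enrichment in place of length. For replicate overlap they were a reciprocal overlap of 50%, a -log10 q of at least 5 and equal numbers of strongest peaks. For CpG class, observed/expected ratios of at least 0.6 and below 0.4 were also used. The functions were tested on simulated data. Promoter overlap and domain length matched a brute-force search for all 719 protein-coding genes of chromosome 19, each at its most 5' TSS. Among 200 random lists of 24 genes drawn from the 21938 genes with no simulated effect, 5% were called for marking and 5% for domain length, or 4.5% and 4% with CpG matching. Calls here were at an unadjusted p under 0.05. When 95% of the members of such lists were marked, 97% of the lists were called, and when their domains were 2 times as long, 99.5% were. Genes were simulated independently, and lengths without regard to CpG class. Lists of clustered genes that share domains, and CpG matching of length, were thus not put to the test. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.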

Results

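H3K4me3 was profiled by ChIP-seq in embryonic mouse hearts at day 11.5, when the tube has looped and chambers, valves and outflow tract are forming. The group held 2 biological replicates of pooled hearts. Peak lists of 32154 peaks for replicate 1 and 35017 for replicate 2 were deposited with a pooled list of 30715 and a replicated list of 25868 peaks. Replicated peaks covered 37.9 Mb, or 1.39% of the chromosomes, with a median width of 1236 bp and a median fold enrichment of 17.5. The number of reads behind each list is unknown.

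Most peaks were found in both replicates. On the main chromosomes, 83.9% of the peaks of replicate 1 overlapped a peak of replicate 2, and 75.1% of those of replicate 2 overlapped one of replicate 1. After 100 random shifts along the chromosomes, the mean overlaps were 2.93% and 2.71%. Shared peaks were strong and wide, with median fold enrichments of 13.8 and 15.4 and median widths of 1065 and 1189 bp in replicates 1 and 2. Peaks present in only 1 replicate had medians of 3.26 and 3.32 for fold enrichment and of 230 and 244 bp for width. Across the 14675 genes marked in both lists, promoter fold enrichment had a Spearman correlation of 0.920 and domain length one of 0.930. These correlations are across genes, which are not independent replicates. Fold enrichment differed by less than 1.5-fold between replicates at 95.4% of the genes.

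Promoters of protein-coding genes held 61.9% of the replicated peaks (95% exact binomial interval 61.3 to 62.5%) and 81.2% of the base pairs they covered. Promoter peaks had a median width of 1783.5 bp and a median fold enrichment of 34.3. Exons held 10.2% of peaks, introns 13.3% and intergenic sequence 14.6%, and their median fold enrichments were 7.12, 4.58 and 6.11. The promoter share was 52.0% and 55.2% in the lists of replicates 2 and 1, which hold more weak peaks.

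Of the 21938 protein-coding genes, 14706 (67.03%) were marked. The replicates' own lists marked 14816.5 ± 51.6 genes (SD, n = 2). Marking followed promoter CpG content. High-CpG promoters were marked in 98.6% of 10642 genes, intermediate ones in 71.5% of 4202 and low-CpG ones in 17.1% of 7094, and the SD of each share between replicates was at most 0.419 percentage points. The odds ratio of high against low was 340 by Fisher's exact test, whose p was below the smallest number the software represents. Classes were set at the most 5' TSS, and with marking also restricted to that TSS the low-CpG share was 8.39%. Median fold enrichment was 45.2 at marked high-CpG promoters and 21.7 at marked low-CpG ones.

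Several of the longest domains lay over regulators of heart development. Hand2, a basic helix-loop-helix factor of the right ventricle and outflow tract, had the longest joined domain of the replicated list, 21335 bp on chromosome 8 from 57315650 to 57336984 in mm10. It ran from upstream of the gene through its body into 2 noncoding genes downstream. Within it, the domain over the Hand2 promoter measured 13629.5 ± 529.6 bp in the replicates' own lists (SD, n = 2), where gaps wider than the joining distance parted the downstream peaks. There Gata4 had the longer domain in both replicates (15307 and 21407 bp, against 13255 and 14004 bp), and without joining Meis2 (13290 bp) lay above Hand2 (12125 bp). Gata4, a zinc finger factor of cardiac mesoderm, followed with 17632 bp on chromosome 14 from 63235502 to 63253133 (18357 ± 4313 bp, n = 2). Meis1 had 14341 bp and Tbx5, a T-box factor of atria and left ventricle, 14194 bp. Gata6 had 13528 bp, Tbx2, a T-box repressor of the atrioventricular canal, 12077 bp and Tbx20 11974 bp. Of the 20 longest domains, 7 lay at genes of the cardiac transcription factor list and 1 at Igf2, a fetal growth factor, with 11594 bp. Others lay outside the fixed lists. They included Smad7 (13750 bp), an inhibitor of TGF-beta and BMP signalling, the homeobox genes Irx5 (13740 bp) and Meis2 (13290 bp), and the H3K4 methyltransferase gene Setd1b (11791 bp). Tnrc18 (13471 bp), Bahcc1 (12862 bp), Pcdh7 (11408 bp), Nr2f1 (10866 bp), Irs1 (10862 bp), Nfib (10440 bp) and Irf2bp2 (10326 bp) were also among them. A domain of 10901 bp joined the promoters of Aloxe3, Hes7 and 9130213A22Rik.

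**Figure D1:**
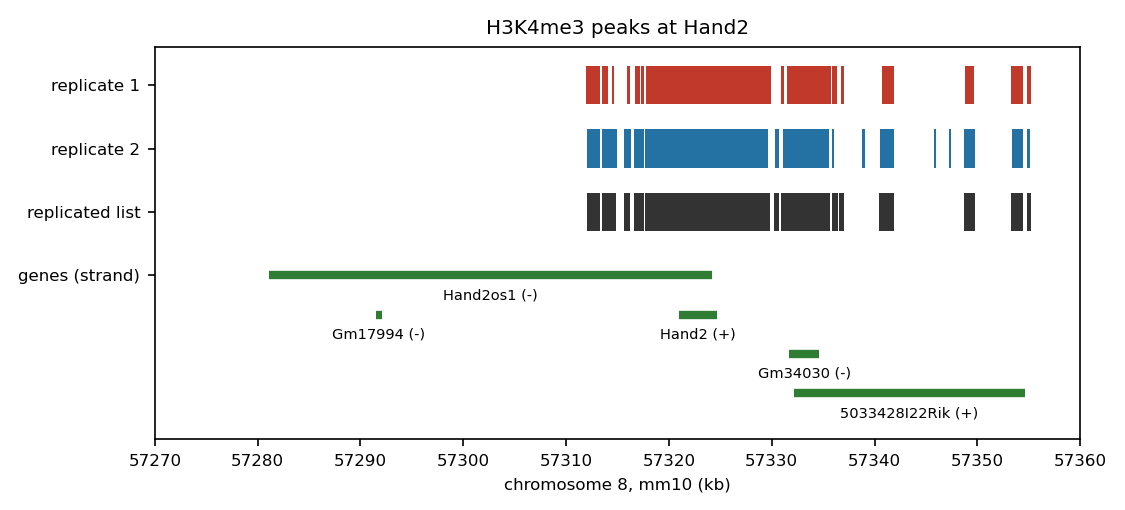
H3K4me3 peaks around Hand2 on chromosome 8 of mm10, with position in kb on the horizontal axis. Bars are the peaks of replicate 1, replicate 2 and the replicated list, and green lines are annotated genes with their strand. The widest replicated peak spans 12125 bp over Hand2 and the start of Hand2os1, a noncoding gene on the opposite strand that overlaps Hand2.

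The genes with the highest peaks were mostly not those with the very longest domains. The highest fold enrichments by the lower of the 2 replicates lay at genes outside the fixed lists, several of them used in most cells. By this rule Phf13, which encodes a reader of H3K4me3, was highest with 70.4 ± 1.78 (SD, n = 2), followed by Yy1 with 68.0 ± 1.02. In the replicated list Phf13 (80.3) lay below several other genes, among them Yy1 (81.9), Pgs1 (82.7) and Rnf10 (82.8). Close behind, in no clear order, were Dhx9 (67.7 ± 2.75), Irf2bp2 (67.6 ± 1.03), the H3K36 demethylase gene Kdm2a (67.4 ± 0.205), the ribosomal protein genes Rpl19 (66.9 ± 1.61) and Rps19 (66.5 ± 0.562), and Serbp1 (66.1 ± 0.00915). Aamdc and Rsf1, which share a promoter domain, had 65.9 ± 0.246. Their domains measured 2539 to 4776 bp, apart from the 10326 bp of Irf2bp2. All were thus longer than the median over marked genes, 2083 bp (quartiles 1528 and 2840 bp). Those of Yy1 and Irf2bp2 were among the longest 5%.

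All 26 cardiac transcription factor genes were marked, and their domains were far longer than those of other genes. The median was 6503 bp, against 2082 bp for other marked genes, and 6146 ± 116.7 bp in the replicates' own lists (SD, n = 2). Nkx2-5, the homeobox factor of cardiac progenitors, had 10145 bp, Hand1 7492 bp, Tbx3, a T-box factor of the conduction system, 7307 bp and Isl1, a marker of cardiac progenitors, 6603 bp. The shortest were Mef2a with 2610 bp and Hopx with 3052 bp. The longest 5% of domains, those of at least 4568.5 bp, took in 22 of the 26. The difference in median length had an adjusted p of 8e-05 by permutation, and the odds ratio for the longest 5% was 107.6 (adjusted p = 5.12e-24, Fisher's exact test). Marking exceeded that of other genes (adjusted p = 0.000208, Fisher's exact test). It also exceeded that of promoters of the same CpG classes, of which 22.4 were expected to be marked (adjusted p = 0.0179, permutation within classes), but with only the most 5' TSS this call was lost, at 25 marked against 21.96 expected (adjusted p = 0.0556, and 0.0128 to 0.0556 over the alternatives). By fold enrichment in place of length the list did not stand apart, with a median of 43.1 against 40.1.

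Neural transcription factor genes, taken as developmental regulators of another tissue, were also all marked (26 of 26), but their domains were shorter. Their median length was 2631.5 bp, 3871.5 bp below that of the cardiac factors (adjusted p = 4e-05, permutation test). Pou3f2 (5431 bp) was the only member among the longest 5%, and Otx1 had 4441 bp, Dlx2 4317 bp and Pax6 3398 bp. Random lists of their CpG classes had 24.8 marked members, which left little room for an excess (adjusted p = 0.676, permutation within classes). Median fold enrichment was 17.4, against 40.1 for other marked genes, and the small excess in length over other genes (adjusted p = 0.0431, permutation test) was lost in several settings, among them either replicate's list alone, where medians were 2118 and 2647 bp.

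Sarcomere and contractile genes were marked without exception, 26 of 26, although 15 of them had low-CpG promoters. Random lists of the same CpG classes had 12.3 marked members on average (adjusted p = 0.00115, permutation within classes). Their median domain of 4703 bp (4515 ± 413 bp in the replicates, SD, n = 2) exceeded the 2082 bp of other marked genes (adjusted p = 8e-05, permutation test), and 14 were among the longest 5%. Myh7, the beta myosin heavy chain, had 10030 bp, Tpm1, alpha tropomyosin, 9209 bp, Actc1, cardiac alpha actin, 8387 bp and Tnnc1, cardiac troponin C, 6971 bp. In replicates 1 and 2 Actc1 had 5751 and 8274 bp and Tnnc1 6796 and 3558 bp. Myh6, the alpha myosin heavy chain, had 6463 bp, Mybpc3 6091 bp and Tnnt2, cardiac troponin T, 4764 bp, whereas Myoz2 had 1308 bp and Tcap 1719 bp. These domains were long but not high. Median fold enrichment was 24.9, below the 40.1 of other marked genes, so the direction turned when fold enrichment replaced length, but it did not pass against the 29.7 of the same CpG classes (adjusted p = 0.537, 0.000444 to 0.537 over the alternatives, permutation within classes).

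Skeletal muscle genes were marked less often than sarcomere genes of the heart. Of 25, 10 were marked, against 26 of 26 (adjusted p = 2.05e-06, Fisher's exact test), and the median domain was 3439 bp shorter (adjusted p = 5.33e-05, permutation test). The myogenic regulators Myf5 and Myog and the fast myosins Myh1 and Myh2 had no replicated peak at their promoters, but not all myogenic regulators were unmarked. Acta1, skeletal alpha actin, was marked over 3506 bp at a fold enrichment of 5.46 (845 and 3154 bp in replicates 1 and 2). Mylpf was marked over 3428 bp at 62.02 and Actn3 over 2058 bp at 64.9. Both of these domains lay mostly upstream of the annotated gene, and whether they belong to promoters of neighbouring genes was not tested. Myl1 was marked over 1410 bp at 4.58 (1323 and 517 bp in replicates 1 and 2). Myod1, also a myogenic regulator, was marked over 1153 bp at 4.4. Against all other genes, the low marked share (40%) had an adjusted p of 0.0136 by Fisher's exact test and the short median of 1264 bp one of 0.0103 by permutation, but neither call held against promoters of the same CpG class in the main setting. The length call did with the list of replicate 1 alone, at 940 bp (adjusted p = 0.0133, and 0.0008 to 0.139 over the alternatives, permutation within classes), and by fold enrichment in place of length, at 7.16.

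Genes for ion channels, calcium handling and cell junctions were marked in 20 of 22 cases (adjusted p = 0.0279, Fisher's exact test), with a median domain of 3642.5 bp (adjusted p = 8e-05, permutation test) and 7 among the longest 5%. By fold enrichment in place of length their median of 31.7 lay below 40.1, short of the threshold, with 0 in the top 5%. Jph2, a junctional membrane protein, had 7247 bp, Atp2a2, the calcium pump of the sarcoplasmic reticulum, 6726 bp, the sodium-calcium exchanger Slc8a1 6707 bp and Ryr2, the calcium release channel, 6321 bp. The pacemaker channel gene Hcn4 had 4891 bp and Gja1, connexin 43, 4977 bp. Casq2 and Sln were unmarked. Neuronal effector genes were marked about as often, 22 of 24 (adjusted p = 1, Fisher's exact test), but had a median of 1763.5 bp, 1879 bp shorter (adjusted p = 4e-05, permutation test). Their longest were Gad1 (2985 bp), Celf4 (2901 bp), Nefm (2741 bp) and Snap25 (2447 bp), and Slc17a6 and Dcx were unmarked. The marked shares of both lists no longer passed the threshold with only the most 5' TSS, at 86.4% and 79.2%.

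Chamber hormone and growth factor genes were all marked (12 of 12, adjusted p = 0.0169, Fisher's exact test, a call lost with only the most 5' TSS, at 11 of 12), and 5 were among the longest 5%. Igf2, Bmp7 (7714 bp), Fgf9 (7172 bp), an epicardial and endocardial mitogen for myocardium, and Adm (5450 bp), adrenomedullin, led them. Bmp7 had 7700 bp in replicate 2 but 4838 bp in replicate 1, below Fgf9 (7241 bp) and Adm (5285 bp) there. The natriuretic peptide genes Nppa and Nppb, which lie next to each other, had 1807 and 2668 bp at fold enrichments of 8.6 and 14.5. The list's median was 3637 bp (adjusted p = 0.0012, permutation test), and with only the most 5' TSS it was 2787 bp and not past the threshold. By fold enrichment the medians of this list and of the next, 29.5 and 28.2, lay below 40.1, short of the threshold, with 0 members in the top 5%. All 13 genes of the second heart field and outflow tract list were marked (adjusted p = 0.0124, Fisher's exact test, lost with only the most 5' TSS, at 12 of 13), with a median of 4120 bp (adjusted p = 0.000133, permutation test). Wnt5a had 8092 bp, the forkhead genes Foxc1 and Foxc2 7855 and 7730 bp, Plxnd1 6720 bp and Wnt11 6531 bp. Against their CpG classes, with 12.01 expected, there was little room for an excess (adjusted p = 0.765, permutation within classes).

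**Figure D2:**
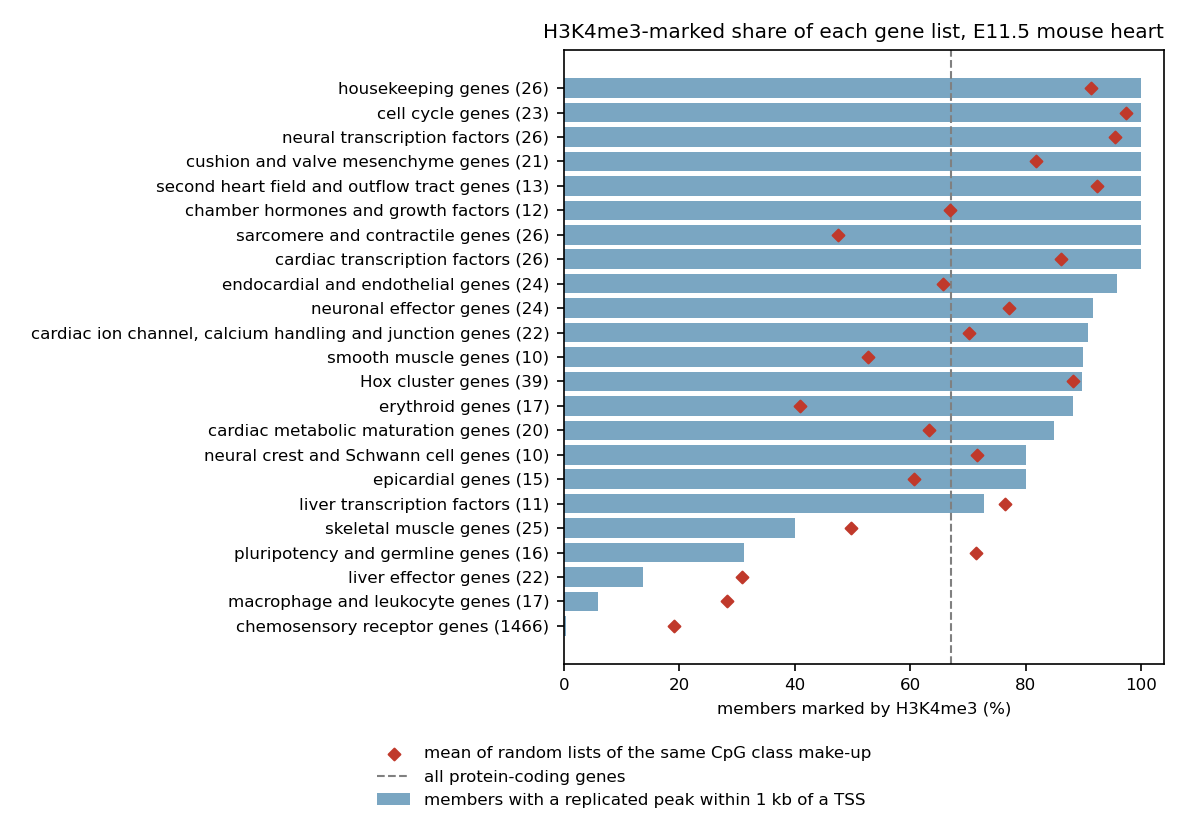
Share of each gene list's members, in percent on the horizontal axis, whose promoter overlapped a replicated peak, with the number of members in brackets. Bars are the observed shares, diamonds the mean of random lists of the same CpG class make-up and the dashed line all protein-coding genes (67.03%). Sarcomere and erythroid genes lie far to the right of their diamonds, and germline, macrophage and chemosensory receptor genes to the left.

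Promoters of endocardial and endothelial genes were marked in 23 of 24 cases (adjusted p = 0.00368, Fisher's exact test, a call lost with only the most 5' TSS, at 20 of 24), against 15.8 expected for their CpG classes (adjusted p = 0.00184, permutation within classes). Their median domain was 4204 bp (adjusted p = 8e-05, permutation test), with 8 among the longest 5%. Nfatc1, an endocardial factor required for valves, had 8871 bp, Npr3 6889 bp, Egfl7 5656 bp and the ETS factor Fli1 4954 bp. Kdr, a VEGF receptor, had 4316 bp and the junction protein genes Cdh5 and Pecam1 3062 and 2403 bp. Robo4 was unmarked. The median fold enrichment of 18.0 lay below the 40.1 of other marked genes, so that the direction turned with fold enrichment in place of length. Macrophage and leukocyte genes, by contrast, were marked in 1 of 17 cases, below other genes (adjusted p = 2.6e-06) and below endothelial genes (adjusted p = 8.09e-09, Fisher's exact test). The marked gene was Cd14 (1636 bp), the only member with a high-CpG promoter, and Ptprc, Csf1r, Cx3cr1 and Adgre1 had no peak in any replicate's list. They were also under-represented against their CpG classes, where 4.8 were expected (adjusted p = 0.0251, permutation within classes). That call was lost with the 2500-bp promoter window, at 2 marked against 5.14 expected (adjusted p = 0.128), and with only the most 5' TSS (adjusted p = 0.1265), and over the alternatives the adjusted p ranged from 0.0167 to 0.128 (permutation within classes).

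Cushion and valve mesenchyme genes were all marked (21 of 21, adjusted p = 0.00073), with a median domain of 3856 bp (adjusted p = 8e-05, permutation test) and 8 among the longest 5%. Fold enrichment in place of length turned the direction (31.7 against 40.1), short of the threshold, with 0 in the top 5%. Pdgfra had 9008 bp, Twist1, a factor of mesenchymal transition, 6898 bp, the hyaluronan synthase gene Has2 5348 bp and Tgfb2 5201 bp, whereas Postn, periostin, had 1115 bp at a fold enrichment of 4.58. Epicardial genes did not stand apart from all other genes in marking, 12 of 15 (adjusted p = 0.451), or in length, with a median of 2007 bp (adjusted p = 0.807, permutation test). Against their CpG classes marking passed with the pooled list and the list of replicate 2, at 13 of 15 each. By fold enrichment in place of length their median of 20.8 lay below 40.1 (adjusted p = 0.0148, and 0.0148 to 0.912 over the alternatives, permutation test), but did not pass against the 31.8 of their CpG classes. Wt1 had 4712 bp, Tbx18 4352 bp, Tcf21 2919 bp and Aldh1a2, which makes retinoic acid, 2416 bp, and Upk1b, Msln and Gpm6a were unmarked. In replicates 1 and 2 Wt1 had 3667 and 6576 bp. For neural crest and Schwann cell genes, 8 of 10 were marked (adjusted p = 0.537) with a median of 2279 bp (adjusted p = 0.673, permutation test). Ednrb had 4147 bp, Ngfr 2979 bp, Tfap2a 2509 bp and Foxd3 2386 bp, and Plp1 and Phox2b were unmarked. Tfap2a had 5212 bp in replicate 1 and 2497 bp in replicate 2. Smooth muscle genes were marked in 9 of 10 cases (adjusted p = 0.208, Fisher's exact test), above the 5.26 expected for their CpG classes (adjusted p = 0.0173, permutation within classes). Tagln had 3417 bp, Acta2 3224 bp, Cald1 2834 bp and Smtn 2590 bp, Actg2 was unmarked, and the median of 2404 bp had an adjusted p of 0.508 by permutation.

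Markers of red blood cells were also present. Erythroid genes were marked in 15 of 17 cases, which did not pass against all other genes (adjusted p = 0.0923, Fisher's exact test), but only 6.96 were expected for their CpG classes (adjusted p = 0.00115, permutation within classes). Against all other genes marking passed at 16 of 17 with the list of replicate 1 alone (adjusted p = 0.0241, Fisher's exact test). It also passed at 16 of 17 with the 2500-bp promoter window (adjusted p = 0.0249, Fisher's exact test). Tal1, a haematopoietic factor, had 8296 bp, Slc4a1, the red cell anion exchanger, 5598 bp, Hemgn 5569 bp and Ank1 5027 bp. The embryonic globin genes Hba-x, Hbb-bh1 and Hbb-y had 3238, 1877 and 1657 bp, whereas Hbb-bt and Hba-a1 were unmarked. Globin genes have near-identical copies, whose reads can be left unplaced, so a missing peak there is uncertain. Median fold enrichment was low, 9.99 ± 2.03 (SD, n = 2), and 10.5 in the replicated list against 40.1 for other marked genes. The median domain of 3238 bp exceeded that of other genes (adjusted p = 0.00483, permutation test), a call lost with the list of replicate 2 alone (2763 bp) and with only the most 5' TSS (2166.5 bp), and turned without joining of peaks (1768 bp).

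Effector genes of liver, germline genes and chemosensory receptor genes were mostly unmarked. Liver effector genes were marked in 3 of 22 cases (adjusted p = 2.63e-06), against 26 of 26 sarcomere genes (adjusted p = 8.01e-10, Fisher's exact test). Alb, Afp, Apoa1 and Apoa2 had no peak, and the marked genes were Apoh (3323 bp), Vtn (1488 bp) and Trf (782 bp). Of their CpG classes 6.77 were expected, and the deficit against those did not pass (adjusted p = 0.0897, permutation within classes) except with the 500-bp promoter window, at 2 against 6.59 (0.0192 to 0.47 over the alternatives). Transcription factors of liver were marked in 8 of 11 cases (adjusted p = 1) with a median of 3318.5 bp (adjusted p = 0.0216, permutation test), a call lost without joining of peaks (2826 bp). Prox1, which the heart also uses, had 8063 bp, Hnf1b 4061 bp, Nr5a2 3937 bp and Onecut1 3343 bp, and Hnf4a, Hnf1a and Nr1h4 were unmarked. Pluripotency and germline genes were marked in 5 of 16 cases, below other genes (adjusted p = 0.0102, Fisher's exact test) and below the 11.4 expected for their CpG classes (adjusted p = 0.00115, permutation within classes). Pou5f1, Nanog, Dppa5a and Ddx4 were unmarked, and Gdf9 (2191 bp), Dazl (790 bp), Dppa3 (675 bp) and Tdrd1 (537 bp) were marked, with a list median of 675 bp (adjusted p = 0.00142, permutation test). Of 1466 chemosensory receptor genes, 4 were marked (0.273%), against 278.3 expected for their CpG classes. Vmn1r4 (5092 bp) and Olfr94 (1247 bp) had fold enrichments of 56.3 and 29.0, and Olfr658 and Olfr1033 had 316 and 315 bp at 6.26 and 4.78. Olfr1416, Olfr1415, Olfr1414 and Olfr1413 were among the unmarked. Whether peaks at the marked genes of these lists belong to promoters of neighbouring genes was not tested.

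Hox cluster genes were marked in 35 of 39 cases (adjusted p = 0.00368, Fisher's exact test), a call lost with only the most 5' TSS (31 of 39). For their CpG classes 34.4 were expected, and their domains were short. The median was 1470 bp, 1594 ± 317 bp in the replicates (SD, n = 2), against 2084 bp for other marked genes (adjusted p = 0.0014, permutation test), and the median fold enrichment was 8.18. The longest were Hoxa1 (4658 bp), Hoxb2 (3537 bp), Hoxa2 (3427 bp) and Hoxb4 (3271 bp), and Hoxc8, Hoxc11, Hoxc12 and Hoxd12 were unmarked. With the list of replicate 2 alone the median was 1818.5 bp and no longer past the threshold.

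Genes used by dividing cells and by all cells were marked throughout, 23 of 23 cell cycle genes (adjusted p = 0.000488) and 26 of 26 housekeeping genes (adjusted p = 0.000208, Fisher's exact test). For their CpG classes 22.4 and 23.7 were expected, which left little room for an excess. The cyclin D genes Ccnd2 (8083 bp) and Ccnd1 (6219 bp) had the longest domains of the cell cycle list, followed by Mki67 (4481 bp) and Plk1 (4126 bp). Actb (5251 bp), Gapdh (5142 bp), Hmbs (4494 bp) and Ywhaz (4071 bp) led the housekeeping list. Median lengths of 3029 and 2965 bp exceeded those of other genes (adjusted p = 0.00255 for both, permutation test), and 2 genes of each list were among the longest 5%, which did not pass (adjusted p = 0.704 and 0.721) but did at 5 of each with peaks joined up to 2000 bp. With only the most 5' TSS the housekeeping median was 2549 bp and not past the threshold. Genes of the mature heart's metabolism were marked in 17 of 20 cases (adjusted p = 0.12, Fisher's exact test), which exceeded the 12.7 expected for their CpG classes (adjusted p = 0.0276, permutation within classes). Esrrg, a nuclear receptor, had 6663 bp (4001 and 4831 bp in replicates 1 and 2). The glucose transporter gene Slc2a4 had 4419 bp, Ppargc1a 4402 bp and Lpl 3487 bp, and Ckmt2, Mb (myoglobin) and Ucp3 were unmarked. Their median of 2239 bp was 2464 bp below that of sarcomere genes (adjusted p = 0.00026, permutation test), but by fold enrichment, added for this pair after seeing the data, it lay above (30.4 against 24.9), which did not pass (adjusted p = 0.398, 0.0001 to 0.398 over the alternatives, permutation test). The marked shares of 85% and 100% did not differ past the threshold (adjusted p = 0.113, Fisher's exact test).

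**Figure D3:**
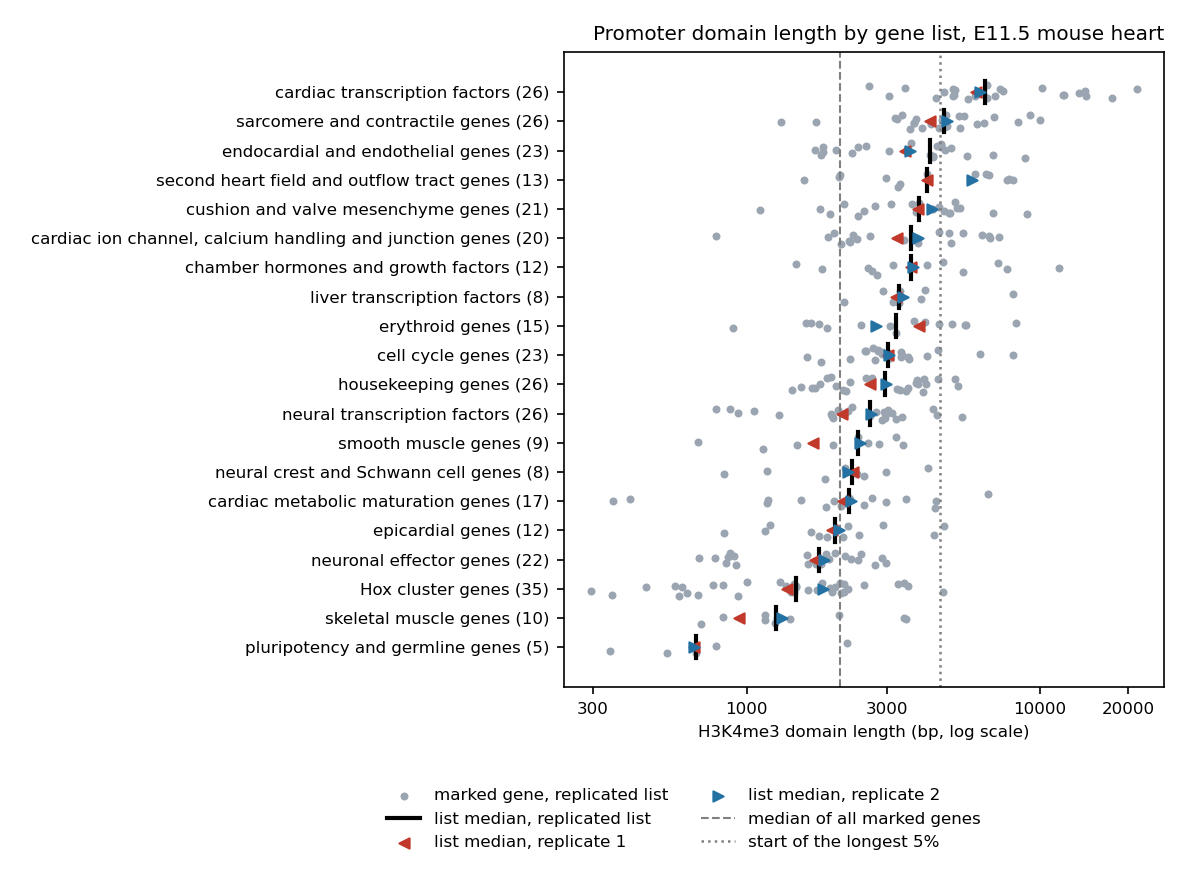
H3K4me3 domain length in bp (horizontal axis, log scale) of the marked members of 20 gene lists, with their number in brackets. Grey points are genes and black bars list medians in the replicated list, triangles are the medians in each replicate, and the lines mark the median of all marked genes (2083 bp) and the start of the longest 5% (4568.5 bp). Cardiac transcription factors have the highest median, 6503 bp, and germline genes the lowest, 675 bp.

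Of the 23 lists, 8 were over-represented among the longest 5% of domains: cardiac transcription factors, sarcomere, ion channel, chamber, outflow tract, endothelial, cushion and erythroid genes. With peaks joined up to 2000 bp 12 passed, the added ones being epicardial (3 members), Hox (6), cell cycle (5) and housekeeping genes (5). By fold enrichment in place of length no list passed (0 of 23 by Fisher's exact test with adjustment), and 1 passed at an unadjusted p under 0.05, the housekeeping genes with 5 members. The erythroid call (4 members, adjusted p = 0.0157, Fisher's exact test) was lost with only the most 5' TSS and without joining, at 2 members each, and the count was 8 with the list of replicate 1 alone.

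Among noncoding genes linked to heart development, several were marked. Hand2os1 shared the domain of Hand2. Mir1a-1, a muscle microRNA, lay in a domain of 7964 bp (7364 ± 1612 bp, SD, n = 2) and Mir1a-2 in one of 3484 bp (3697 ± 290 bp, n = 2). Fendrr, next to Foxf1, had 4755 bp (5065 ± 2370 bp, SD, n = 2). The imprinted genes H19 and Meg3 had 3475 and 3013 bp, and Bvht had 456 bp at a fold enrichment of 6.21. Mir126a, Mir133a-1, Mir133a-2, Mir208a, Mir208b and Mhrt had no replicated peak within 1 kb of their annotated start. Mature microRNAs are cut from longer transcripts, so the annotated start of a microRNA need not be its promoter.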

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

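Apart from the main chromosomes, 11 replicated peaks lay on unplaced or unlocalised sequences of mm10, which no comparison used. They drew attention because they are signal outside the main measurement. The strongest, at 15512 to 17572 of an unlocalised sequence of chromosome 4, had a fold enrichment of 36.98 and a -log10 q of 184.6. Next came a peak at 38354 to 39648 of an unlocalised sequence of chromosome X, with a fold enrichment of 27.4. The replicates' own lists held 10 and 13 such peaks. No explanation was tested. With 2 replicates in 1 group, neither a sample far from the others nor a difference between groups could be examined.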

How the results depend on the processing

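All settings were planned, except 1 for the pairs of lists. No paired analysis was possible because there is only 1 group. The number of marked genes stayed between 13918 and 14911 and the excess of high over low CpG promoters between 74.4 and 90.2 percentage points in every setting. In the planned pairs of lists, 7 or 8 comparisons passed in every planned setting. By fold enrichment in place of length, added for the pairs after seeing the data, 6 passed and the difference between sarcomere and metabolic genes turned to -5.46 (24.9 against 30.4), which did not pass (adjusted p = 0.398, 0.0001 to 0.398 over the alternatives, permutation test). Cardiac transcription factors still lay above neural ones by fold enrichment (43.1 against 17.4, adjusted p = 4e-05, permutation test). So did ion channel genes above neuronal effector genes (31.7 against 12.9, adjusted p = 4e-05) and sarcomere above skeletal muscle genes (24.9 against 7.16, adjusted p = 0.00323, permutation test). Where a call changed, the cause was not tested. The promoter share of peaks moved from 61.9% to 67.2% at the stricter q, 55.7% in the pooled list, 59.5% and 69.0% with 500- and 2500-bp windows, 50.5% with only the most 5' TSS, and 52.0 to 55.2% with 1 replicate left out. Replicate sharing of 79.3% became 66.4% at 50% reciprocal overlap, 93.3% at the stricter q and 81.1% with equal numbers of peaks, and the correlation of fold enrichment was 0.915 at the stricter q.

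Marking differed in 17 lists, and in 11 with only the most 5' TSS, where the shares of ion channel (86.4%), chamber (91.7%), outflow tract (92.3%), endothelial (83.3%), neuronal effector (79.2%) and Hox genes (79.5%) no longer passed. Against random lists matched on promoter CpG class the shares of outflow tract, neural transcription factor, cell cycle and housekeeping genes (each 100%), neuronal effector (91.7%), Hox (89.7%), skeletal muscle (40%) and liver effector genes (13.6%) no longer passed, because the expected share changed, and lists at 100% had little room to exceed it. Neither did the median lengths of neural transcription factor (2631.5 bp) and skeletal muscle genes (1264 bp). The CpG-matched call of cardiac transcription factors was lost with only the most 5' TSS, and that of macrophage genes there and with the 2500-bp window.

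Lengths that no longer passed with only the most 5' TSS were those of chamber (2787 bp), erythroid (2166.5 bp), neural transcription factor (2415 bp) and housekeeping genes (2549 bp). Without joining of peaks the erythroid median of 1768 bp fell below that of other genes, and liver transcription factors (2826 bp) and neural transcription factors (2095 bp) did not pass. The latter also missed the threshold in the pooled list (2631.5 bp) and with the promoter window of 500 bp (2643 bp). With 1 replicate left out, medians ranged from 2763 to 3882.5 bp for erythroid, 2118 to 2647 bp for neural transcription factor and 1370 to 1818.5 bp for Hox genes. The 2 erythroid members in the broadest domains with only the most 5' TSS, and the 2 without joining of peaks, did not pass, and with 1 replicate left out the count was 4 to 8.

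With peaks joined up to 2000 bp, 12 lists in place of 8 were over-represented among the broadest domains, the added ones being epicardial, Hox, cell cycle and housekeeping genes. With fold enrichment in place of length, 0 lists were over-represented among the broadest domains (1 at an unadjusted p under 0.05, Fisher's exact test). There, 1 cardiac transcription factor gene and 0 sarcomere, 0 ion channel, 0 chamber, 0 outflow tract, 0 endothelial, 0 cushion and 0 erythroid genes were in the top 5%. Median fold enrichment was 43.1 for cardiac transcription factor and 46.1 for cell cycle genes, which did not pass. It lay below that of other genes for sarcomere (24.9), ion channel (31.7), chamber (29.5), outflow tract (28.2), endothelial (18.0), cushion (31.7), erythroid (10.5), neural transcription factor (17.4), liver transcription factor (26.2), neural crest (14.8) and smooth muscle genes (18.9). Epicardial genes lay lower too (20.8). The ion channel, chamber, outflow tract, cushion and liver transcription factor values did not pass in that direction, and against CpG-matched lists neither did the sarcomere, epicardial, neural crest and smooth muscle values. Settings were counted over the descriptive values and the tests that passed in the main setting. Of these, 442 kept the call or stayed within the spread, 32 lost the threshold, 13 moved and 19 turned direction. All 19 were in domain length or the broadest domains, where a count of 0 members also counted as a turn. Among tests that did not pass in the main setting, 8 settings gained the threshold and 2 passed in the other direction. Depth is unknown, so its limits cannot be stated.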

Other observations

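Gene families were grouped by symbol after the values were seen and were not tested, and some of their members are in the fixed lists. All 6 Irx homeobox genes were marked with a median of 6869 bp (6709 ± 27.6 bp in the replicates, SD, n = 2), and 5 of them were in the longest 5% of domains, led by Irx5, Irx2 and Irx1. All 6 Gata genes were marked with a median of 9720 bp (9388 ± 624 bp, n = 2), led by Gata4, Gata6 and Gata3, but 4 of the 6 are genes of the fixed lists. Of 19 Sox genes 18 were marked, with a median of 3209 bp and 6 in the longest 5%, led by Sox11, Sox4 and Sox12, and of 44 forkhead genes 37 were marked, with a median of 2784 bp. Ribosomal protein genes combined a high median fold enrichment of 54.0 with a median length of 2666.5 bp, and clustered histone genes a low one of 16.4 with 2927 bp. Of 49 keratin genes 9 were marked, against 321 of 365 Zfp zinc finger genes, whose domains were short, with a median of 1692 bp.

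Long noncoding RNA genes away from coding promoters were marked in 875 of 7796 cases (11.2%), with a median domain of 1170 bp. Those in the longest domains shared them with coding neighbours such as Hand2, Meis1, Tbx20 and Setd1b, but Malat1 had 9448 bp of its own on chromosome 19. A further 8408 replicated peaks (32.5%) overlapped no promoter window of any annotated gene. They were weak, with a median fold enrichment of 5.26 and a median width of 545.5 bp, and 48.6% lay within 10 kb of an annotated TSS. Only 40 of them reached a fold enrichment of 40.1, the median over marked genes of the highest promoter peak. That is a stricter mark than the median of 34.3 of single promoter peaks. Among these were a peak of 3253 bp in an intron nearest to the start of Arhgap23 (chromosome 11, 97439787 to 97443039, fold enrichment 60.3), one of 4799 bp nearest to that of Kdm6b (chromosome 11, 69407784 to 69412582, 55.8) and an intergenic one of 2891 bp, 73555 bp from the nearest start, that of Tln2 (chromosome 9, 67631814 to 67634704, 50.2). All 3 were in both replicates. The most significant replicated peak of all, with a -log10 p of 599.5, lay near Hjurp on chromosome 1 from 88275708 to 88278070 at a fold enrichment of only 30.3, whereas the next 9 by p had 68.3 to 82.8. No list of regions of artefactual signal or variable copy number was used, so what that p means is open.

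The tests of promoter CpG content below were planned as alternatives but chosen as tests of a cause after the result was seen, and the others before it. The first pattern was the long domains of cardiac transcription factor and contractile genes. Both lists stayed longer than random marked lists matched on promoter CpG class (permutation p = 0.0002 at most), on promoter fold enrichment (0.0002) and on the number of annotated TSSs (0.0002), which is the smallest p these could give. The difference also held among genes whose domain held no other protein-coding gene's promoter (2e-05, permutation test, the smallest it could give). Medians were 6503 and 4648 bp against 1944 and 1945 bp. Promoters of noncoding genes, such as those in the domains of Hand2, Meis1 and Tbx20, were not removed there. These results argue against each of the 4 as the whole cause, but the last test speaks only on joined promoters of coding genes. The hypothesis that long domains mark genes that set the identity of the heart may hold, but with 1 tissue in the design no biological explanation was tested.

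The other pattern at cell type markers was the marked erythroid promoters. CpG content could not account for it (p = 0.0002, permutation within classes), and it did not rest on the globin genes, since all 12 other members were marked, against 6.13 expected (p = 0.0002, permutation within classes), a test that decides nothing on near-identical globin copies, whose unplaced reads can only lower marking. Blood in the dissected hearts is a candidate source: the median promoter fold enrichment of the erythroid genes was 0.422 of that of sarcomere genes (p = 0.002, permutation test), the lower level predicted for a minor cell population, and the labels name no step that removes blood. The embryonic globin genes Hba-x and Hbb-bh1 had low values, 7.58 ± 1.37 and 7.499 ± 2.197 (SD, n = 2). But endothelial and neural transcription factor genes also had low medians (18.0 and 17.4), so a low level is not particular to blood. Tal1 and Tfrc are used by other cells. Over the alternatives the adjusted p of marking ranged from 0.0241 to 0.682 against all other genes (Fisher's exact test), and it was 0.00115 against the same CpG classes.

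The last pattern was the short domains of Hox genes. Joining peaks across gaps up to 2000 bp left the median below that of other genes, 1739 against 2161 bp (adjusted p = 0.0439, permutation test), which argues against unjoined peaks as the whole cause. The difference shrank from -614 to -422 bp, and 6 of the 35 genes in place of 1 were then among the longest 5% of domains (odds ratio 3.95), so a contribution of unjoined peaks stays open. The adjusted p ranged from 5.71e-05 to 0.133 over the alternatives, and the call was lost with the list of replicate 2 alone, at 1818.5 bp. Medians were 2085 bp in groups 1 to 5 (1818 and 2037 bp in replicates 1 and 2), 1446 bp in groups 6 to 8 (872 and 1827 bp) and 766 bp in groups 9 to 13 (766 and 955.5 bp), with p = 0.00014 between the first and the last (permutation test), consistent with the untested hypothesis that anterior more than posterior Hox genes are active in part of the heart at this stage.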
